A study of Homo sapiens with 9 samples.

How the data were processed

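RNA from LX-2, an established human hepatic stellate cell line, was sequenced in 9 libraries on the BGISEQ-500 instrument. All cells had received TGFβ1 at 10 ng/ml, per the labels. The libraries form 3 groups of 3: a negative control siRNA, an siRNA against LOX and an siRNA against LOXL1. The targeting siRNAs were used at 25 nM for 48 hours, per the series design; the dose of the control siRNA and the sequences of the siRNAs are not given in the sources used here. The treatment label of control replicate 3 differs from that of its partners in leaving out the word siRNA, and the library was kept in the control group on its title. The sources do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

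The authors deposited FPKM values, fragments scaled to transcript length and to the mapped total of the library, for 17123 genes, with 2 decimals, per the file headers and the values. The submitters' processing notes name TopHat2 2.0.10 and the hg19 build. The tool that made the FPKM values is not given in the sources used here. The gene positions in the table do not follow hg19: of the gene IDs, 17086 were matched to a GRCh38.p14 gene table, and 91.4% of these had starts within 5000 bases of that table. Positions are therefore given as the table holds them and read as GRCh38; 381 genes lie on alternate contigs. All 17123 genes list protein-coding transcript accessions, so noncoding and mitochondrially encoded genes are not in the table and were not analysed here. The table holds no read counts, so no counting interval is given. The lowest values above 0 of 369 low, single-transcript genes, read as 1 fragment each, gave a median FPKM times length of 57.9 to 59.4 per library, so depth was near equal between libraries if that reading holds. FPKM values divide by length and total, so a library whose fragments favour short or GC-rich transcripts shifts whole classes of genes.

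FPKM values were analysed as log2(FPKM + 1), with a pseudocount of 1. Genes with an FPKM of 1 or more in at least 3 of the 9 libraries were tested, which kept 11808 genes. One limma model of 3 groups was fitted over all 9 libraries (limma 3.58.1 in R 4.3.3, empirical Bayes with a mean-variance trend, 6 residual degrees of freedom), and each pair of groups was compared by a contrast in it. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05 and no fold threshold. Fold changes are differences of mean log2(FPKM + 1) with their standard error (SE). The pseudocount makes them smaller in size than log2 ratios of mean FPKM, most of all for genes of low FPKM. Group levels are mean FPKM ± SD with n = 3. An exact permutation test of 3 libraries against 3 cannot give a p under 0.1, so single genes rest on the limma model.

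Gene lists, 36 in number, were fixed before the data were examined; 34 had at least 3 tested members. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists, then with camera's estimated correlation and with fry. The p-values of single members were also adjusted over each list alone. That adjustment was not extended across the 34 lists, so some calls of that kind would be met by chance. Named genes followed a rule fixed at the same time. It took both targeted genes, then up to 12 rises and 12 falls per knockdown (6 of each in the direct comparison) among genes past the threshold with a mean of at least 5 FPKM and groups that did not overlap, and up to 4 members of each list by smallest p. Genes named outside the rule are said to be so.

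On simulated values for the 11808 genes, with 67 genes changed by log2 0.5, the model recovered 91.0% of them for LOX siRNA against control, 95.5% for LOXL1 siRNA against control and 94.0% between the knockdowns. For a change of 0.25, given to 67 other genes, the shares were 56.7%, 52.2% and 56.7%, and 66 more genes were changed by 1. These simulated runs gave 170 to 174 calls, where the real comparisons gave 1, 9 and 25. The Benjamini-Hochberg adjustment is stricter where fewer genes pass, so these shares are likely too high for the real comparisons. Overlap between the knockdowns was set against 100 simulations of unchanged groups that share the controls, because both comparisons use the same 3 control libraries. Control libraries this few cannot be divided into parts of at least 2.

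Alternatives chosen before the data were examined were median-ratio scaling, quantile normalization, limma without the trend, no filter, a mean FPKM of 5 or more, a pseudocount of 0.1, the compared groups alone, the replicate number as a block, a log2 fold threshold of 1, camera's estimated correlation and each library left out. One was added after the data were seen: removal of each library's trend on transcript length and GC content with natural splines of 4 degrees of freedom, for the 98.6% of tested genes with a transcript GC value.

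For the closing section, 3' UTR sequences came from GENCODE release 29 (GRCh38), 1 transcript per gene, for 11476 tested genes with a 3' UTR of at least 50 bases. Each of 16323 words of 7 bases found in at least 30 of these genes was scored by a rank-sum z of the log2 difference between a knockdown and the mean of the other 2 groups. That difference was first regressed on 3' UTR length and GC, mean expression, transcript length and transcript GC. The same was done with words of 8 bases. Forms without this regression, or without transcript GC in it, and forms with other contrasts of the groups, were also looked at while the analysis was developed. The word scan was tested on simulated data and returned the planted word. That test was easier than the real scan: the planted shift was larger than those reported below, genes were drawn independently and no regression was applied. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.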

Results

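Transcript levels were measured in LX-2 cells, a human hepatic stellate line that takes on myofibroblast features under TGFβ1, after transfection with control, LOX or LOXL1 siRNA. LOX and LOXL1 encode secreted amine oxidases that start the cross-linking of collagen and elastin. Each group held 3 libraries. The deposited FPKM values summed to between 384881 and 396088 per library, and 11663 to 11728 genes reached an FPKM of 1 in each. Pearson's r of log2 values across genes was 0.996 to 0.998 within groups and 0.995 to 0.997 between groups, and no pair of libraries shared the same value in more than 0.720% of tested genes.

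The first question was whether each siRNA lowered its own target. LOX (gene ID 4015, chromosome 5, 122063200 to 122078500 on the minus strand) fell from 46.2 ± 2.94 FPKM (SD, n = 3) in control libraries to 28.4 ± 2.67 with LOX siRNA. That is a fall of 38.5% in mean FPKM, with a log2 fold change of -0.68 on the log2(FPKM + 1) scale (SE 0.06, limma, adjusted p = 6.73e-04). LOXL1 (gene ID 4016, chromosome 15, 73926458 to 73952141 on the plus strand) fell from 12.3 ± 1.11 to 6.80 ± 0.997 FPKM with LOXL1 siRNA, a log2 fold change of -0.78 (SE 0.09; adjusted p = 0.00432). Without the filter on low values the adjusted p of LOXL1 was 0.0632, the highest of its alternatives, and with each library left out it ranged from 0.00611 to 0.0298. Each fall was seen in 3 of 3 libraries, all below the lowest control. LOX stood at 51.1 ± 1.39 FPKM with LOXL1 siRNA (log2 fold change 0.14, SE 0.06; adjusted p = 0.456). LOXL1 stood at 11.7 ± 0.959 FPKM with LOX siRNA (log2 fold change -0.07, SE 0.09; adjusted p = 0.910). Among the other family members, LOXL2 had 88.3 ± 5.46, 88.0 ± 1.87 and 87.3 ± 1.47 FPKM in the control, LOX siRNA and LOXL1 siRNA groups. LOXL3 had 2.39 ± 0.222, 2.69 ± 0.137 and 2.37 ± 0.267 FPKM in the same order, and neither gene passed the test in any comparison.

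**Figure D1:**
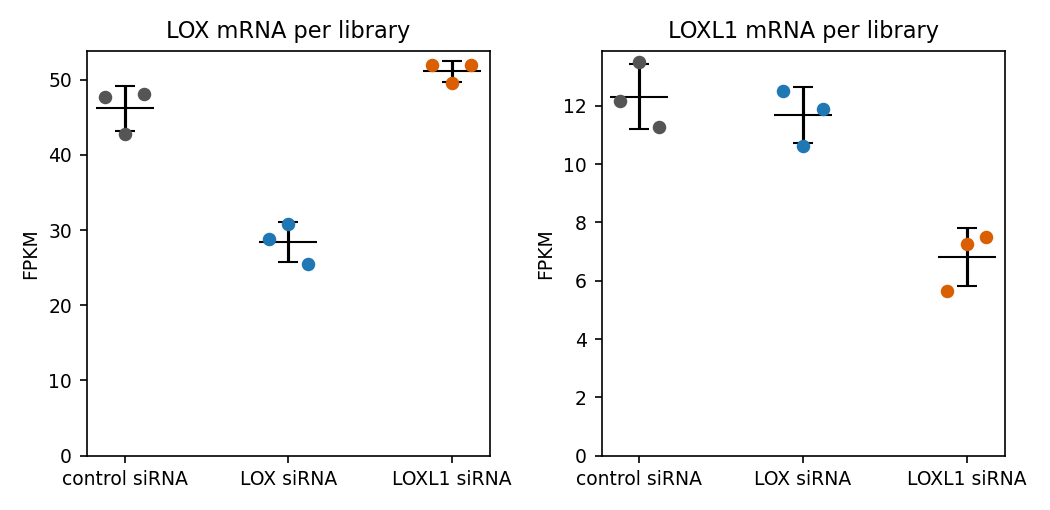
FPKM of LOX (left) and LOXL1 (right) in each of the 9 libraries by siRNA group; points are libraries, horizontal bars group means and whiskers ± SD (n = 3). LOX lies at 28.4 ± 2.67 FPKM with LOX siRNA against 46.2 ± 2.94 in control libraries, and LOXL1 at 6.80 ± 0.997 with LOXL1 siRNA against 12.3 ± 1.11.

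The comparison of LOX siRNA with control asked which transcripts follow a partial loss of LOX mRNA in TGFβ1-treated stellate cells. LOX itself was the 1 gene of 11808 that passed the threshold, and without LOX siRNA replicate 1 there were 2. At an unadjusted p under 0.05 there were 818 genes, where 590.4 would be met by chance, and 12.8% of genes had groups that did not overlap, against 10% by chance. These chance values have no spread attached and genes are not independent. An excess over them, here or in the comparisons below, is therefore not read as a response. Of genes central to fibrosis, the 3 named here, chosen after their values were seen, did not pass. COL1A1, the main chain of type I collagen, had a mean of 228 FPKM against 237 in control (log2 fold change -0.05, SE 0.06). ACTA2, smooth muscle actin, had 7.54 ± 0.802 against 7.51 ± 0.622 FPKM (log2 fold change 0.0033, SE 0.08). TIMP1, an inhibitor of matrix proteases, had a log2 fold change of -0.01 (SE 0.09).

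Under camera's preset correlation, small shifts of whole gene groups accompanied LOX siRNA. Camera called 4 of 34 lists in that form, and fry called 0. None of the 34 lists passed camera with an estimated correlation, the smallest adjusted p being 0.449. Of 35 cytosolic ribosomal protein genes, 35 had a fold change above 0, with a median log2 fold change of 0.097 (camera with a preset correlation, adjusted p = 2.88e-15, and adjusted p = 0.449 with an estimated correlation). Adjusted over the list alone, 10 of them rose, and 0 rose over all genes tested. RPS29 stood at 225 ± 10.6 FPKM against 191 ± 8.15 (log2 fold change 0.23, SE 0.05), RPL7 at 375 ± 8.78 against 339 ± 4.45 (0.14, SE 0.03) and RPL11 at 707 ± 20.7 against 643 ± 4.99 (0.14, SE 0.04). Nuclear genes of oxidative phosphorylation were above 0 in 24 of 26 members, with a median of 0.069 (camera adjusted p = 5.49e-06, and adjusted p = 0.449 with an estimated correlation). SDHB, a subunit of succinate dehydrogenase, rose when adjusted over the list alone, from 54.3 ± 0.179 to 60.7 ± 1.89 FPKM.

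Matrix and adhesion lists leaned the other way. Of 17 tested collagen chain genes, 14 were below 0 (median log2 fold change -0.056, camera adjusted p = 0.00817, and adjusted p = 0.747 with an estimated correlation). COL8A1, a short-chain collagen, fell when adjusted over the list alone (16.1 ± 0.312 to 14.1 ± 0.793 FPKM), and 0 collagens passed over all genes. Of 21 integrin and focal adhesion genes, 15 were below 0 (median -0.049, camera adjusted p = 0.0221, and adjusted p = 0.449 with an estimated correlation), ITGA6 having a log2 fold change of -0.10 (SE 0.05) and TLN1, talin, of -0.08 (SE 0.04). The collagen call was lost without control replicate 2 (median -0.035, adjusted p = 0.310) and without LOX siRNA replicate 3 (median -0.012, adjusted p = 0.659), over a range of 5.71e-05 to 0.659 with each library left out; without the filter it was lost too (adjusted p = 0.144). The integrin call was lost without the same libraries (adjusted p = 0.112 and 0.325, over a range of 0.00794 to 0.325 with each library left out) and without the filter (0.0523). Its median was -0.0376 without control replicate 2 and -0.043 without LOX siRNA replicate 3. Each of the 3 LOX siRNA libraries gave lower values to longer transcripts (Spearman's rho of -0.285, -0.279 and -0.249 across genes between a library's deviation and transcript length). With length and GC trends removed, the ribosomal list had a median of 0.056 (adjusted p = 6.08e-07, and adjusted p = 0.0541 with an estimated correlation), while the oxidative phosphorylation list (median 0.037, adjusted p = 0.112), the collagen list (median -0.0077, adjusted p = 0.991) and the integrin list (median -0.0098, adjusted p = 0.420) did not pass.

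The comparison of LOXL1 siRNA with control asked the same of LOXL1. Here 9 genes passed, 2 higher and 7 lower, with 1208 genes at an unadjusted p under 0.05 and 14.3% of genes in groups that did not overlap, against 10% by chance. HAS2 (chromosome 8, 121613030 to 121641390), which encodes a hyaluronan synthase, rose from 8.95 ± 0.357 to 12.2 ± 0.526 FPKM (log2 fold change 0.41, SE 0.05; adjusted p = 0.00432). C11orf74 rose to 17.3 ± 0.899 FPKM (log2 fold change 0.29, SE 0.05; adjusted p = 0.0490). AKIRIN1 (chromosome 1, 38991244 to 39006065) fell from 23.7 ± 0.775 to 17.8 ± 1.05 FPKM (log2 fold change -0.39, SE 0.05; adjusted p = 0.00432). CDC23 (chromosome 5, 138187650 to 138213340), a subunit of the anaphase-promoting complex, fell from 24.9 ± 0.571 to 19.96 ± 0.441 FPKM (log2 fold change -0.31, SE 0.04; adjusted p = 0.00432). VOPP1 (chromosome 7, 55470608 to 55572520) fell from 48.8 ± 1.93 to 39.2 ± 0.804 FPKM (log2 fold change -0.31, SE 0.04; adjusted p = 0.00432). MICB, a ligand of the NKG2D receptor, fell from 24.1 ± 1.03 to 20.1 ± 0.287 FPKM (log2 fold change -0.25, SE 0.04; adjusted p = 0.0490). AGAP9, which fell (log2 fold change -0.32, SE 0.05; adjusted p = 0.0179), belongs to a family of near-identical copies, so its level is uncertain. NPTXR, a neuronal pentraxin receptor that lies below the level the naming rule asks for and was chosen after its values were seen, fell from 3.32 ± 0.206 to 1.91 ± 0.0473 FPKM (log2 fold change -0.57, SE 0.07; adjusted p = 0.00432).

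LOXL1, HAS2, AKIRIN1, CDC23, VOPP1 and NPTXR passed with each of the 9 libraries left out in turn. C11orf74 and MICB were lost in 8 of those 9 fits each (highest adjusted p = 0.225 for both, without control replicate 1) and AGAP9 in 5 (highest 0.121, without control replicate 1). Without LOXL1 siRNA replicate 3 there were 14 calls. With length and GC trends removed there were 30, which included the same 9 genes. The fibrosis genes named above did not pass: the log2 fold change was -0.09 (SE 0.06) for COL1A1, -0.10 (SE 0.08) for ACTA2 and 0.04 (SE 0.09) for TIMP1.

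At the level of gene groups, mitotic genes stood higher and several matrix, immune and lipid lists lower with LOXL1 siRNA, under camera's preset correlation. None of the 34 lists passed with an estimated correlation, the smallest adjusted p being 0.645. Fry called 1 list, integrins (adjusted p = 0.0142), where camera called 12. Of 28 mitosis and G2/M genes, 27 were above 0 (median log2 fold change 0.063, camera adjusted p = 1.91e-06, and adjusted p = 0.645 with an estimated correlation). AURKB, a mitotic kinase, stood at 77.2 ± 0.943 against 71.5 ± 1.84 FPKM, and DLGAP5, a spindle protein, at 58.8 ± 1.95 against 53.2 ± 2.90; 0 members rose when adjusted over the list alone. All 17 tested collagen chain genes were below 0 (median -0.093, camera adjusted p = 2.25e-04, and adjusted p = 0.645 with an estimated correlation), COL4A1 at 29.3 ± 0.988 against 33.4 ± 1.35 FPKM and COL18A1 at 46.5 ± 1.77 against 51.4 ± 1.95; 0 fell when adjusted over the list alone. These lists passed with each library left out and with the length and GC trends removed (mitosis median 0.041, collagen median -0.048, and adjusted p = 0.803 for both with an estimated correlation).

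Of 28 interferon-stimulated genes, 25 were below 0 (median -0.091, camera adjusted p = 0.00165, and adjusted p = 0.680 with an estimated correlation), and STAT2, a subunit of the interferon-response factor ISGF3, fell when adjusted over the list alone (log2 fold change -0.19, SE 0.04). Of 24 cholesterol synthesis genes, 20 were below 0 (median -0.055, camera adjusted p = 0.00240, and adjusted p = 0.680 with an estimated correlation), and 4 fell when adjusted over the list alone, among them SREBF2 (log2 fold change -0.15, SE 0.04) and HSD17B7 (-0.16, SE 0.05). SREBF2 encodes the regulator of the pathway. Lysosome and autophagy genes (20 of 23 below 0, median -0.039, camera adjusted p = 0.0187, and adjusted p = 0.645 with an estimated correlation) included ATG9A, which fell when adjusted over the list alone (54.1 ± 0.607 to 48.6 ± 1.07 FPKM). Among p53 targets (17 of 22 below 0, median -0.045, camera adjusted p = 0.0207, and adjusted p = 0.724 with an estimated correlation), BBC3, which encodes the pro-apoptotic protein PUMA, fell when adjusted over the list alone (7.07 ± 0.221 to 5.49 ± 0.471 FPKM). NF-kB and cytokine genes were below 0 in 19 of 24 (median -0.117, camera adjusted p = 0.0177, and adjusted p = 0.800 with an estimated correlation), with CSF1 at 11.8 ± 1.19 against 14.3 ± 1.43 FPKM and ICAM1 at 91.5 ± 9.29 against 104 ± 3.43. Without LOXL1 siRNA replicate 1 the median of that list was 0.042 (adjusted p = 0.716), and 4 more of these lists were lost. Their medians were then -0.039 for interferon (adjusted p = 0.128), -0.024 for cholesterol (0.152), -0.0037 for p53 (0.750) and -0.033 for lysosome genes (0.107), the last little moved. The call of the NF-kB and inflammatory cytokine genes was also lost without control siRNA replicate 1 (adjusted p = 0.0856), control replicate 2 (0.141) or LOXL1 siRNA replicate 2 (0.122). The interferon call was lost without LOXL1 siRNA replicate 2 (0.0508), the p53 call without control replicate 1 (0.0816) and the lysosome call without control replicate 3 (0.0919). Without LOXL1 siRNA replicate 1, 2 lists passed in place of 12, and without LOXL1 siRNA replicate 2 or control replicate 1 there were 7 in each case.

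The remaining calls lay near the threshold. Collagen-modifying enzymes (16 of 19 below 0, median -0.058, camera adjusted p = 0.0207, and adjusted p = 0.680 with an estimated correlation), stellate cell quiescence and lipid genes (8 of 9 below 0, median -0.079, camera adjusted p = 0.0365, and adjusted p = 0.645 with an estimated correlation) and integrins (15 of 21 below 0, median -0.047, camera adjusted p = 0.0489, and adjusted p = 0.645 with an estimated correlation) were lower. With length and GC trends removed none of these 3 passed (adjusted p = 0.605, 0.605 and 0.397). Without control replicate 2 none did (medians -0.0419, -0.0305 and -0.0257, adjusted p = 0.353, 0.335 and 0.0814). Without LOXL1 siRNA replicate 1 none did either (medians -0.064, -0.0636 and -0.0288, adjusted p = 0.128, 0.152 and 0.107). Without LOXL1 siRNA replicate 2 the enzyme list had an adjusted p of 0.0905 and the integrin list one of 0.178, the integrin call being lost in 8 of 9 fits and with median-ratio scaling (0.0606). LHX2, a transcription factor of quiescent stellate cells, fell when adjusted over the quiescence list alone (log2 fold change -0.21, SE 0.05), as did ITGB5 (10.8 ± 0.503 to 8.80 ± 0.196), ITGA7 and ITGA3 over the integrin list. Myofibroblast contractile genes (15 of 18 above 0, median 0.033, camera adjusted p = 0.0420, and adjusted p = 0.724 with an estimated correlation) and YAP and TEAD targets (15 of 23 above 0, median 0.032, camera adjusted p = 0.0489, and adjusted p = 0.645 with an estimated correlation) were higher. With length and GC trends removed the contractile median was 0.059 (camera adjusted p = 1.93e-04, and adjusted p = 0.803 with an estimated correlation). The YAP median was then 0.042 (camera adjusted p = 0.00730, and adjusted p = 0.381 with an estimated correlation). The contractile call was lost without control replicate 1 (median 0.0143, adjusted p = 0.305), control replicate 3 (0.0115, adjusted p = 0.387) or LOXL1 siRNA replicate 1 (0.0125, adjusted p = 0.299). It was also lost with median-ratio scaling (adjusted p = 0.0502) or quantile normalization (0.0990). The YAP call was lost without control replicate 1 (adjusted p = 0.0816), control replicate 3 (0.195), LOX siRNA replicate 1 (0.0521), LOXL1 siRNA replicate 1 (0.638) or LOXL1 siRNA replicate 2 (0.0680), and with median-ratio scaling (0.0550) or quantile normalization (0.0807). F3, tissue factor, and ANKRD1 rose when adjusted over the YAP list alone, F3 from 46.7 ± 1.95 to 54.6 ± 3.11 FPKM.

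**Figure D2:**
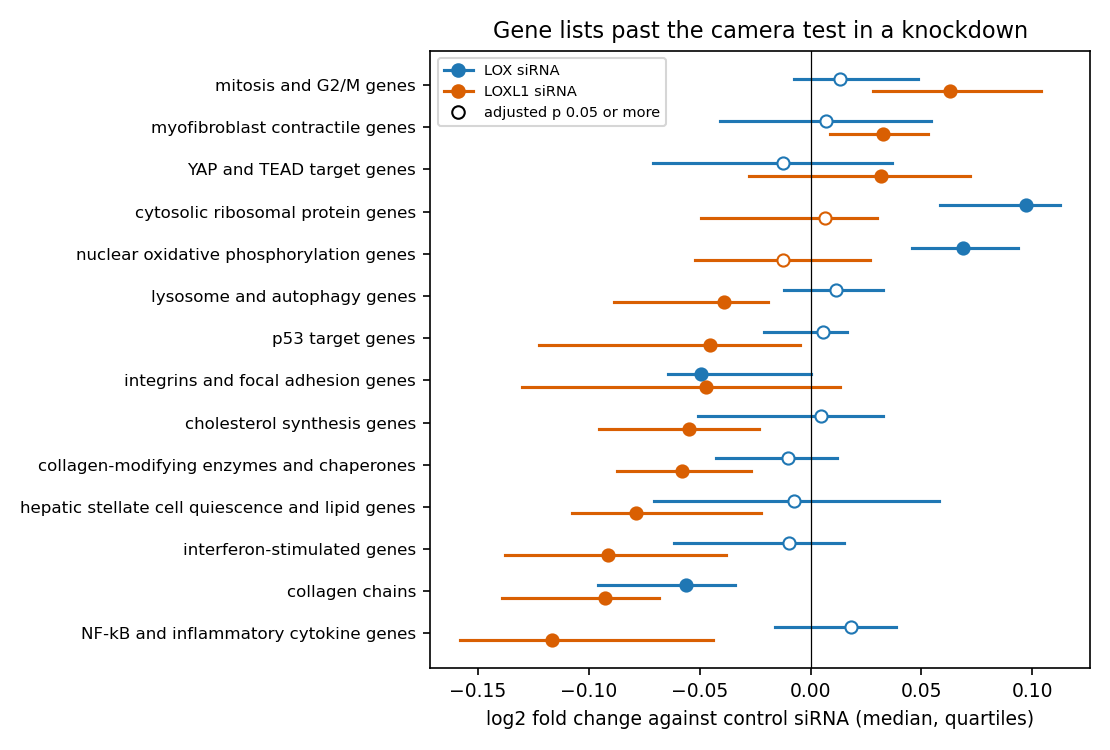
Median log2 fold change against control siRNA of the members of each gene list that passed camera at its preset correlation in at least 1 knockdown; points are medians, bars span the quartiles of the members, and open points mark an adjusted p of 0.05 or more. Ribosomal protein genes have a median of 0.097 with LOX siRNA, and collagen chains one of -0.056 with LOX siRNA and -0.093 with LOXL1 siRNA.

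The direct comparison asked which genes differed between the knockdowns. There were 25 calls, 17 higher and 8 lower with LOX siRNA, and 1513 genes at an unadjusted p under 0.05; 21.5% of genes had groups that did not overlap, against 10% by chance. LOX (log2 fold change -0.83, SE 0.06; adjusted p = 6.64e-05) and LOXL1 (0.71, SE 0.09; adjusted p = 0.00630) differed as their siRNAs would direct. AKIRIN1 (0.45, SE 0.05), CDC23 (0.36, SE 0.04) and VOPP1 (0.34, SE 0.04) were higher with LOX siRNA, as was HMOX1, heme oxygenase (23.6 ± 0.916 against 18.9 ± 0.825 FPKM). HAS2 (-0.36, SE 0.05), TAF13 (26.4 ± 0.563 against 34.1 ± 1.93 FPKM), PEG10 (10.8 ± 0.236 against 13.8 ± 0.762) and RPIA (9.11 ± 0.331 against 11.6 ± 0.387) were lower. KRTAP2-3 (27.4 ± 1.91 against 40.3 ± 4.89 FPKM) was lower too, and its near-identical family members make its level uncertain. Of the 25 genes, 4 (LOX, AKIRIN1, CDC23 and VOPP1) passed with each library left out. Without LOX siRNA replicate 2, TAF13 (adjusted p = 0.0946) and PEG10 (0.132) were lost, and without LOX siRNA replicate 3, LOXL1 (0.0520), HAS2 (0.122), HMOX1 (0.193), RPIA (0.193) and KRTAP2-3 (0.197). In all, HMOX1, RPIA and KRTAP2-3 were lost in 6 of 9 fits each, TAF13 and PEG10 in 4, HAS2 in 3 and LOXL1 in 1.

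This count moved with single libraries, from 5 without LOX siRNA replicate 2 or 3 to 56 without control replicate 2. It was 6 without LOXL1 siRNA replicate 1, 9 without LOX siRNA replicate 1, 13 without LOXL1 siRNA replicate 2, 14 without control replicate 1 and 39 without LOXL1 siRNA replicate 3. Camera at its preset correlation gave 11 lists. Ribosomal protein genes (33 of 35 above 0, median 0.094; adjusted p = 8.71e-10, and adjusted p = 0.526 with an estimated correlation) and oxidative phosphorylation genes (24 of 26 above 0, median 0.084; adjusted p = 4.34e-05, and adjusted p = 0.526 with an estimated correlation) were higher with LOX siRNA, with 14 and 4 members rising when adjusted over the list alone. Mitosis genes (24 of 28 below 0, median -0.045; adjusted p = 5.48e-04, and adjusted p = 0.576 with an estimated correlation) and YAP and TEAD targets (17 of 23 below 0, median -0.045; adjusted p = 7.96e-04, and adjusted p = 0.314 with an estimated correlation) were lower. Without LOX siRNA replicate 3 the mitosis list had a median of -0.019 (adjusted p = 0.0687). With length and GC trends removed the median was 0.051 for oxidative phosphorylation (adjusted p = 0.00958, and adjusted p = 0.121 with an estimated correlation) and -0.026 for YAP and TEAD targets (adjusted p = 0.00210, and adjusted p = 0.115 with an estimated correlation). Lysosome and autophagy genes (20 of 23 above 0, median 0.061, adjusted p = 7.96e-04, and adjusted p = 0.314 with an estimated correlation) were higher in each of the 9 fits with a library left out. The other 6 lists were each lost without at least 1 library: without LOXL1 siRNA replicate 1 the cholesterol (adjusted p = 0.239), p53 (0.715), NF-kB (0.715) and interferon (0.457) lists, and without LOX siRNA replicate 3 the ATF4 (0.171) and contractile (0.664) lists. None of the 34 lists passed with an estimated correlation, the smallest adjusted p being 0.314, and fry called 1, lysosome and autophagy genes (adjusted p = 0.0308).

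The overlap between the knockdowns was 0 genes called in both, with limma. As LOX siRNA gave 1 call, LOX itself, almost no overlap was possible. At an unadjusted p under 0.05 there were 169 genes in both with the same direction. Shared controls alone give such genes, and their number in unchanged groups was not simulated, so this count is no measure of a common response. Independent lists of these sizes would share 5.93e-04 lower genes. Across genes, which are not independent replicates, the fold changes of the knockdowns had a Pearson's r of 0.365, where unchanged groups gave 0.496 against shared controls. Over the libraries left out, r ranged from 0.253 without LOXL1 siRNA replicate 3 to 0.556 without control replicate 3; the simulated value holds for 3 libraries per group, so it is no yardstick for these. The covariance was 0.00246, against 0.00298 (SD 2.74e-04 over 100 simulations) for unchanged groups. Fold changes had the same sign in 62.5% of genes, against 66.6% in the simulations. The simulations drew each gene independently, without the length and GC trends of the real libraries. Their SD is therefore too small to judge these gaps, and no lack of shared movement is read from them. The controls are too few to divide, so part of any shared movement may come from them.

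**Figure D3:**
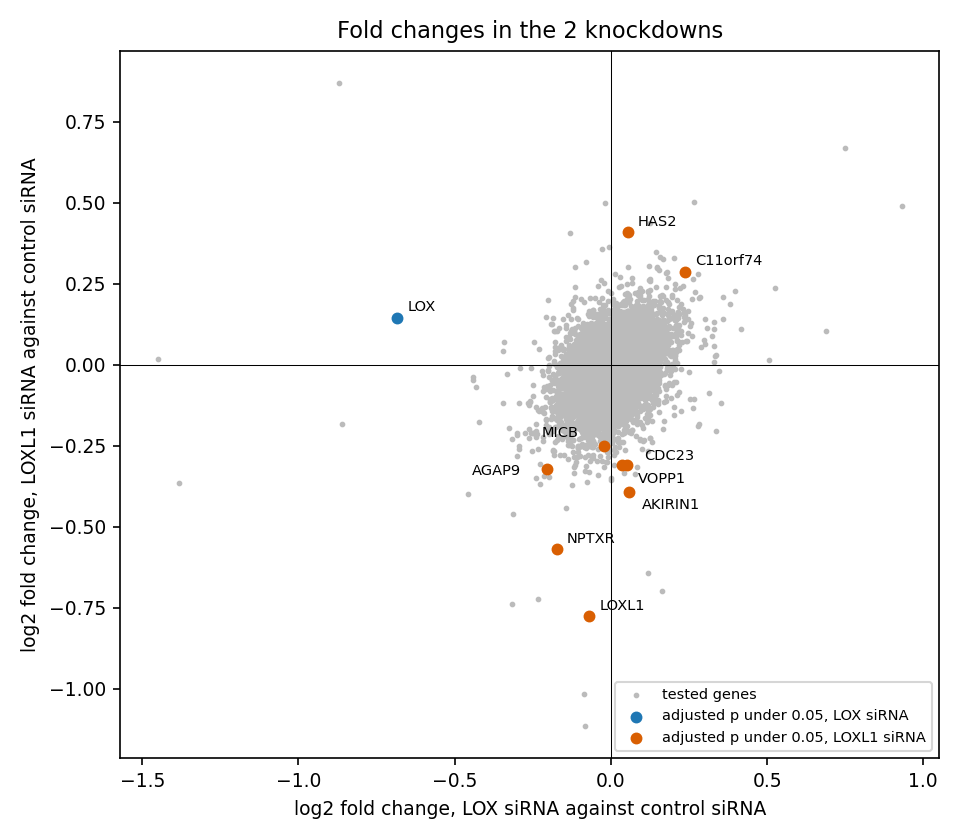
Log2 fold change of each of the 11808 tested genes with LOX siRNA (horizontal) and LOXL1 siRNA (vertical), both against control; coloured points are genes with a limma adjusted p under 0.05 in one of them. LOX lies at -0.68 horizontally and LOXL1 at -0.78 vertically, and no gene is coloured for both.

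Libraries of a group did not stand fully apart from the rest. The first principal component of the 500 most variable genes held 26.3% of the variance and the second 15.7%. LOXL1 siRNA libraries lay farthest apart on the first, replicates 1 and 2 at 6.06 and 3.51 and replicate 3 at -4.18. Library deviations followed transcript GC content in control replicate 2 (Spearman's rho 0.696 across genes), while control replicates 1 and 3 lay at -0.055 and -0.290. The LOX siRNA libraries lay between -0.016 and 0.167, and the LOXL1 siRNA libraries all below 0, between -0.308 and -0.219. Markers of other liver cell types did not pass camera in either knockdown with all libraries, and the cholangiocyte and epithelial list passed without LOX siRNA replicate 1 (median -0.11, adjusted p = 0.0407). Adjusted over the list alone, the mucin gene MUC1 fell with LOX siRNA (5.82 ± 0.698 to 4.79 ± 0.150 FPKM) and the endoglin gene ENG with LOXL1 siRNA (121 ± 4.36 to 112 ± 1.39 FPKM). TAT, the most abundant hepatocyte marker, had a mean of 0.741 FPKM over all libraries, so that list was not tested. The epithelial keratins KRT18 (214, 216 and 209 FPKM in control, LOX siRNA and LOXL1 siRNA) and KRT8 (91.1, 91.6 and 88.0 FPKM) were expressed in all groups.

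**Figure D4:**
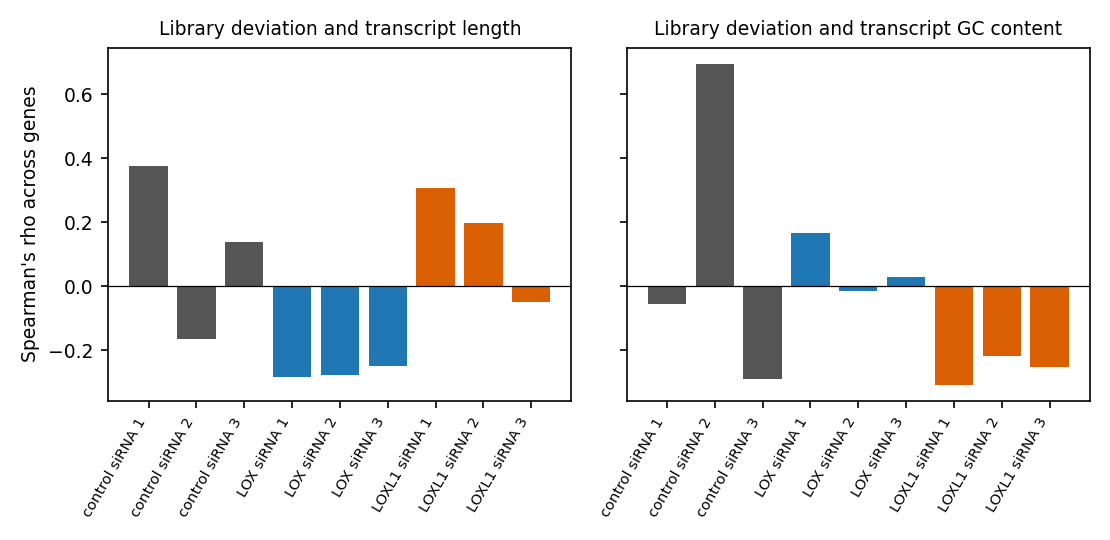
Spearman's rho across genes between each library's deviation from the mean log2 value and transcript length (left) or transcript GC content (right), 1 bar per library, coloured by group. The 3 LOX siRNA libraries lie between -0.285 and -0.249 for length, and control replicate 2 at 0.696 for GC content.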

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

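Removal of the length and GC trends was the alternative chosen after the data were seen; the others were planned. Every alternative but a fold threshold kept LOX lower with LOX siRNA past the threshold, its log2 fold change lying between -0.74 and -0.61 with each library left out. LOXL1 with LOXL1 siRNA lay between -0.84 and -0.67. Without the filter on low values LOXL1 missed the threshold in both of its comparisons (log2 fold change -0.78, adjusted p = 0.0632, and 0.71, adjusted p = 0.103), where more genes enter the adjustment and the variance trend; without LOX siRNA replicate 3 the second was 0.69 (adjusted p = 0.0520), within 0.60 to 0.77 over the libraries left out.

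Counts of genes for LOX siRNA against control were 2 without the filter and 2 with the trends removed, and 1 to 2 with each library left out. For LOXL1 siRNA against control the count was 30 (4 higher, 26 lower) with the trends removed and 6 to 14 with each library left out. Between the knockdowns it was 11 with quantile normalization (5 higher, 6 lower), 8 without limma's trend (6 higher, 2 lower), 4 without the filter (3 higher, 1 lower) and 5 to 56 with each library left out. A log2 fold threshold of 1 left 0 genes in each of the 3 comparisons. The replicate block gave 15 genes between the knockdowns, 13 of them shared with the 25, where it spends residual degrees of freedom; AGAP9, C11orf74 and MICB also missed the threshold under the block with LOXL1 siRNA, as did the YAP (adjusted p = 0.0612) and integrin (0.0578) lists. Deviations of libraries with the same number had correlations of -0.068 to 0.025, and 0 of 9 libraries correlated best with its own number. No pairing by number was therefore seen in the values. This does not exclude that libraries with the same number were prepared together. No filter gave 1 gene in the overlap of the knockdowns.

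Lists for LOX siRNA against control numbered 2 without the filter, 2 with the trends removed (1 of them among the 4) and 0 with an estimated correlation. With the estimated correlation 0 lists also passed in the other comparisons. With each library left out there were 3 to 6 lists for LOX siRNA, 2 to 14 for LOXL1 siRNA and 7 to 12 between the knockdowns. The NF-kB list turned without LOXL1 siRNA replicate 1, to 0.042 against control and -0.046 between the knockdowns; over the libraries left out it lay between -0.25 and 0.042, and between -0.046 and 0.26. Changes of log2 0.25 were recovered in 52.2% to 56.7% of simulated genes, in runs with 170 to 174 calls.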

Other observations

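Of the tests below, the per-replicate word test and the bounds of both gradings by site length were fixed before their results were seen. The gradings used words picked for the lowest scores in these same libraries, so they are not independent of the word scores. The word scores, the count of genes without a site, the trend tests on lists and the counts of other splits were chosen after, with their bounds set or reworded once results were in view.

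With LOXL1 siRNA, single members of lists that did not pass as a whole differed from control when adjusted over their list alone, and none of those named here passed over all genes (adjusted p = 0.161 to 0.291). Of 17 matrix glycoproteins and proteoglycans, 2 rose and 3 fell when adjusted over the list alone; among them tenascin C, TNC, rose (47.0 ± 1.62 to 52.6 ± 1.83 FPKM, n = 3) and the proteoglycans SDC4 (58.6 ± 0.367 to 53.4 ± 0.757), AGRN (36.2 ± 2.34 to 31.5 ± 1.26) and GPC1 (56.2 ± 3.91 to 49.4 ± 1.06) fell, while camera gave an adjusted p of 0.286 for the list. In the growth factor list FGF5 rose (12.1 ± 0.660 to 13.9 ± 0.306 FPKM) and PDGFRB (7.44 ± 0.269 to 6.34 ± 0.252) and PDGFA (8.86 ± 0.691 to 7.65 ± 0.150) fell, adjusted over that list alone. Of the endoplasmic reticulum chaperones, SDF2L1 (log2 fold change -0.23, SE 0.05) and PDIA6 (-0.15, SE 0.04) fell on the same terms, as did NDRG1 (-0.15, SE 0.04) among hypoxia genes. TGFβ target genes had a median of -0.043 (camera adjusted p = 0.548), with TGFB2 at 20.8 ± 1.34 against 18.5 ± 1.04 FPKM and TGFB1 at 92.5 ± 2.31 against 102 ± 7.24.

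With LOX siRNA, single members of lists that did not pass as a whole differed from control when adjusted over their list alone. With no adjustment across lists, some such calls would be met by chance here and with LOXL1 siRNA. The oxidoreductase gene AKR1C1 rose (3.45 ± 0.644 to 4.67 ± 0.279 FPKM), EGR1 rose (13.7 ± 1.64 to 16.5 ± 0.533), FOSL2 fell (26.5 ± 1.18 to 23.5 ± 0.648) and ASAP1 fell (43.5 ± 1.36 to 37.4 ± 0.187). Their adjusted p over all genes was 0.532, 0.569, 0.532 and 0.423. Replication-dependent histone genes had a median of -0.035 over 11 members (camera adjusted p = 0.118), and one of -0.072 with length and GC trends removed (adjusted p = 0.00106, and adjusted p = 0.0965 with an estimated correlation).

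Many of the genes lower with LOXL1 siRNA share a sequence, and a candidate explanation is seed pairing of the siRNA itself with 3' UTRs of other mRNAs. Of 16323 words of 7 bases, TGCAACA scored lowest (z = -11.0, 1097 genes) and CTGCAAC second (z = -9.52), where the highest score of the opposite sign was 3.90. Together they form CTGCAACA, the lowest of 60202 words of 8 bases (z = -10.3, 331 genes), which occurs once in the LOXL1 mRNA, in the coding sequence of exon 6 of 7 (GRCh38 chromosome 15, 73949550 to 73949557, plus strand); 3.35% of all words of 8 bases occur in that mRNA. TGCAACA was again chosen, and again lowest, when found without replicate 1, 2 or 3 and scored in the replicate left out (z = -8.78, -7.50 and -7.84, below -3 in 3 of 3), which argues against a chance word. Against control siRNA alone, genes with the word of 8 bases had a median log2 change of -0.043 relative to genes without a site (95% bootstrap interval over genes -0.050 to -0.033). Those with 7 bases had one of -0.012 and those with 6 bases one of -0.0067. The same 8-base genes lay at 0.0017 with LOX siRNA, also against control. The word was picked in these libraries, so part of this difference is built in. The interval covers neither that choice nor the spread between libraries.

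Of the 6 called lower genes other than LOXL1, NPTXR, CDC23, AKIRIN1 and VOPP1 carry the word of 8 bases and MICB one of 7, against 19.0% of 11476 searched genes with a site of 7 or 8 bases. The rises of HAS2 and C11orf74 have no site. Sites in the searched 3' UTRs did not cover every called fall. With the trends removed, 5 of the 25 called lower genes other than LOXL1 lack one (AGAP9, VASN, OSGEPL1, FAM72C and ITGB5), where 1.5 false calls would be allowed among 30. VASN, OSGEPL1 and FAM72C were chosen after their values were seen, and AGAP9 and FAM72C have near-identical copies. Coding sequences and other transcripts were not searched, and the LOXL1 match itself lies in coding sequence. The count therefore cannot show that these genes fell without a site. Those genes, and the list shifts, may follow from loss of LOXL1 or from other effects of the transfection, which a design with 1 siRNA group per target cannot separate. The words were sought in several forms of the screen and in the same libraries, and the siRNA sequence is not given in the sources used here, so the pairing is inferred from these libraries alone; a second LOXL1 siRNA with another seed, or LOXL1 restored from a resistant cDNA, would test it.

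A weaker trace of the same kind appeared with LOX siRNA. TTATGAA scored lowest of the words of 7 bases (z = -4.85), where the highest score of the opposite sign, the words of the LOXL1 site left out, was 3.90. CTTATGAA scored lowest of the words of 8 bases (z = -6.07) and occurs once in the LOX mRNA, in the coding sequence of exon 1 of 7 (GRCh38 chromosome 5, 122077413 to 122077420, minus strand). Of all words of 8 bases, 7.17% occur in that mRNA. Against control siRNA, genes with it had a median log2 change of -0.019 relative to genes without a site (95% interval over genes -0.025 to -0.013). The order was 8, 7 and 6 bases, yet the change was short of the 0.02 set beforehand as the least effect to count. This word too was picked in the libraries that graded it. Chosen without one replicate, the word of 7 bases was CTCCCCC once and TTATGAA in the other 2 cases, with z = -2.62, -2.91 and -1.69 in the replicate left out. The word of 8 bases was not scored in this way. Seed pairing by the LOX siRNA and chance therefore cannot be told apart by these tests.

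The ribosomal, oxidative phosphorylation, collagen and integrin shifts with LOX siRNA may partly come from fragment length or GC selection in the libraries, since those libraries gave lower values to longer transcripts. Against the fitted trends as the whole cause, the ribosomal list, 1 of 1 tested, passed camera at the preset correlation with them removed (median 0.097 before and 0.056 after), its members then having median deviations of 0.035, 0.041 and 0.042 in the LOX siRNA libraries and -0.016, -0.00096 and -0.024 in the controls. With an estimated correlation none of the 4 lists passed before or after, the ribosomal list having an adjusted p of 0.449 and then 0.0541. Of the other 3 lists, 0 kept it: the collagen median went from -0.056 to -0.0077 and the integrin median from -0.049 to -0.0098, each by over 50% of its size, while the oxidative phosphorylation median went from 0.069 to 0.037, by less than that. The medians of these 3 lists moved toward 0 as their calls ended. For all 3 lists the length trend and an effect of LOX siRNA cannot be told apart, as short transcripts and the group go together. Removal of the trend would also remove an effect that goes with length. The LOXL1 siRNA libraries all gave lower values to GC-rich transcripts (rho -0.308 to -0.219), as did control replicate 3 (-0.290). List shifts with LOXL1 siRNA may therefore partly come from GC selection too. With the trends removed the collagen median there went from -0.093 to -0.048.

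The 6 libraries of each comparison can be divided in 10 ways, too few for a share under 0.05. In fits of those 6 libraries alone, LOX siRNA against control gave 1 call, the highest other division 2, and 4 of the 10 gave as many. For LOXL1 siRNA against control the values were 6 calls and 4, with 1 division as large, the real one. Between the knockdowns they were 33 calls and 1, again with 1 division as large.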
